A study of Homo sapiens with 8 samples.

How the data were processed

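RNA was sequenced from OV90, an established human ovarian cancer cell line that grows as an epithelial layer on plastic, in 8 libraries. The titles of all 8 libraries carry the mark Neg, whose meaning was not examined. Per the labels' protocols, 4 libraries came from adherent cultures and 4 from spheroids, which are cell clusters grown without attachment, and all cultures ran for 6 days with fresh medium after 72 hours. Adherent cells were given RPMI with 10% tetracycline-free fetal calf serum and 1% penicillin and streptomycin. Spheroids grew in ultra-low attachment vessels in DMEM-F12 without that serum, with 1% of a serum replacement, 1% penicillin and streptomycin, 0.1% insulin, transferrin and selenium supplement, 0.4% bovine serum albumin, EGF at 20 ng/mL and FGF at 10 ng/mL. The medium and the attachment changed together, so every comparison below is between the culture conditions as a whole. Total RNA was purified on columns and libraries were made with a stranded poly(A) mRNA kit, per the labels' protocols. The labels number the replicates 1 to 4 in each group and do not say that they were separate cultures, so p-values measure the spread between these libraries, which may be technical.

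The authors trimmed, aligned and quantified the reads with cutadapt, STAR and RSEM, and used limma, per the submitters' processing notes, which name the builds hg38 and GRCh38; versions and the annotation release are not given in the sources used here. Per the file headers, each library has a table of RSEM gene results with 58381 rows, from which 3 columns were used. The deposited expected counts are RSEM estimates of reads per gene and need not be whole. The deposited TPM values are length-scaled shares of transcripts as RSEM gave them. The effective lengths, a score per gene in bases in the deposited tables, are the gene's mean transcript length less the part in which a fragment cannot start. A deposited table of the whole series holds 31247 genes and is named as voom-normalized, but its values are a linear signal: each deposited value equals the rounded expected count divided by 1 constant per library, with a largest relative deviation of 5.11e-15. That table was used as an alternative only, as log2 of the value plus 1. All of its columns matched a library.

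Expected counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by edgeR's filterByExpr with its minimum count of 10 and minimum total of 15, which left 14829 genes, and libraries were scaled by TMM. Spheroid was compared with adherent by the quasi-likelihood F test over all 8 libraries with no covariate. P-values were adjusted by the Benjamini-Hochberg method and called under 0.05, and changes beyond 2-fold were tested with glmTreat. Fold changes are spheroid over adherent, their standard errors (SE) come from the test statistic, and CPM values are scaled by TMM and given as mean ± SD over 4 libraries. The 38 gene lists, with 558 listed genes of which 477 were tested, were compared with the other genes by camera in limma 3.58.1 with a preset correlation of 0.01, with adjustment over the 38 lists. Camera with an estimated correlation and fry were run beside it. Library measures were compared by the exact two-sided permutation test over 70 assignments, whose smallest p is 0.0286. Current symbols were matched by gene identifier for 56112 rows, and 2 listed histone genes had no row. The pseudoautosomal copies on the Y chromosome, 14 of which passed the filter, were kept in the table and left out of the lists.

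Coordinates of named genes come from RefSeq on GRCh38.p14, the same assembly as the build named in the processing notes. Transcript GC content came from GENCODE transcripts of an older assembly (GRCh37), matched by gene identifier for 99.2% of tested genes, and no coordinate was taken from it. A GC correction, chosen after seeing the data, removed from each library a lowess trend (span 0.3) of log2 CPM (prior count 2) on GC content.

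Before the data were examined, the tests, the lists, the alternatives and the rule for named genes were fixed. The rule takes the 8 largest rises and 8 largest falls among called genes with a mean of at least 10 CPM, no overlap between the groups and a symbol that is not a clone, LOC, LINC or antisense name. From each list it takes up to 2 called members of the prevailing direction and 1 of the other, with the same CPM minimum, or the 2 most abundant members where none was called. MUC16, ALDH1A1, RELA, RELB and MKI67 are named whatever their values, and genes named outside the rule are said to be so. Some genes that the rule takes are not reported here. Alternatives were DESeq2 1.42.0 size factors, upper-quartile and total count scaling, no filter beyond 1 count, a filter at a mean of 10 CPM, the DESeq2 Wald test, limma-voom, limma-trend on the deposited table, an offset for effective length, the replicate number as a block, and leaving out each library. Added after seeing the data were the GC correction, the GC correction without spheroid replicate 1, and the replicate block with the GC correction. For lists, ranges of adjusted p over all alternatives cover these fits, all with the preset correlation. They leave out fry and camera with an estimated correlation, which gave higher values for several lists, such as 0.468 for cholesterol synthesis and uptake.

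Libraries held between 9.06 and 15.4 M expected counts (M for mega). The edgeR steps were tested on simulated counts for the spheroid against adherent comparison, with 14829 genes of which 200 were changed: 14.9% of 1.5-fold, 73.1% of 2-fold and 98.5% of 4-fold changes were recovered, and 6.06% of the calls were false. In the same simulation 18.8% of DESeq2's calls and 5.43% of limma-voom's calls were false. With a GC bias simulated in 1 library, edgeR recovered 4.48% of 1.5-fold, 62.7% of 2-fold and 98.5% of 4-fold changes with 4.35% of calls false, and with the GC correction 26.9%, 80.6% and 97.0% with 6.21% of calls false. Genes encoded in near-identical copies, among them the 7SL RNA genes, HSPA1A and HSPA1B, the metallothioneins, the CEACAM genes and the HLA genes, share reads that RSEM divides by a model, so their values are uncertain.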

Results

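RNA levels of 14829 genes were compared between 4 libraries from spheroids and 4 from adherent cells of the ovarian cancer line OV90. The adherent libraries held 11.6, 11.8, 11.9 and 15.4 M expected counts for replicates 1 to 4, and the spheroid libraries 9.30, 12.1, 11.3 and 9.06 M. The comparison asks how the transcriptome of spheroids in serum-free medium differs from that of attached cells in serum medium.

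In edgeR's quasi-likelihood test 8020 genes (54.1%) changed, 4199 higher and 3821 lower in spheroids, and 1398 changed beyond 2-fold, 993 higher and 405 lower. The first principal component, with 70.4% of the variance, separated the groups. Spheroid replicate 1 lay apart on the second component, with 14.2% of the variance, and its correlation with the other spheroid libraries was 0.948 to 0.957 across genes, against 0.985 to 0.988 among those libraries and 0.987 to 0.990 among adherent libraries. Without it 10271 genes changed, 5204 higher and 5067 lower, and 7937 of the 8020 genes were called in the same direction.

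**Figure D1:**
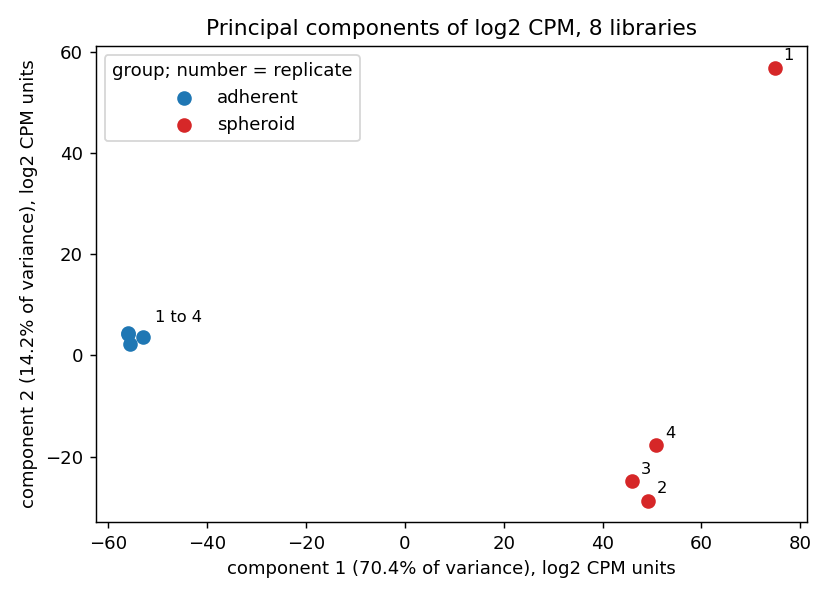
Principal components of log2 CPM over 14829 genes, with component 1 on the horizontal and component 2 on the vertical axis, both in log2 CPM units, and each point a library coloured by group and numbered by replicate. The groups separate on component 1 (70.4% of variance) and spheroid replicate 1 lies apart on component 2 (14.2%).

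The largest rise among genes with a mean of at least 10 CPM was that of PIGR. This gene (ENSG00000162896.5, chromosome 1, 206928522 to 206946466 on GRCh38.p14), the receptor that carries polymeric immunoglobulins across epithelia, rose from 0.290 ± 0.125 to 53.4 ± 5.63 CPM (mean ± SD, n = 4 per group), a log2 fold change of 7.50 with SE 0.20 (edgeR adjusted p = 2.77e-08). CYP1A1 (chromosome 15, 74719542 to 74725528), a cytochrome P450 of xenobiotic metabolism, rose 60.9-fold from 2.54 ± 0.712 to 154 ± 25.5 CPM, and SLC26A3 (chromosome 7, 107765469 to 107803223), an intestinal chloride and bicarbonate exchanger, rose 30.1-fold. OLFM4 (chromosome 13, 53028813 to 53052057), a marker of intestinal crypt cells, rose 23.9-fold to 130 ± 4.15 CPM. HRC (chromosome 19, 49151198 to 49155396) rose 22.0-fold, with 40.4 CPM in spheroid replicate 1 against 19.8 to 22.3 CPM in the other spheroids, and FEZ1 (chromosome 11, 125442881 to 125496265) rose 21.3-fold. HLA-DMB (chromosome 6, 32934636 to 32941028), which helps load peptides on class II molecules, rose 15.3-fold, and BNIP5 (chromosome 6, 36315761 to 36336888) rose 14.6-fold.

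The largest falls were in 4 genes of the 7SL RNA, the RNA of the signal recognition particle. RN7SL2 (chromosome 14, 49862551 to 49862849) fell from 999.5 ± 169 to 21.7 ± 19.3 CPM and RN7SL1 (chromosome 14, 49586580 to 49586878) from 910 ± 168 to 21.7 ± 16.7 CPM, log2 fold changes of -5.54 (SE 0.52, edgeR adjusted p = 2.09e-05) and -5.40 (SE 0.45, edgeR adjusted p = 9.88e-06). RN7SL4P and RN7SL3 had log2 fold changes of -5.39 and -4.36. Spheroid replicate 1 held 50.3 CPM of RN7SL2 and 46.4 CPM of RN7SL1, and the other spheroids 8.72 to 16.1 and 11.6 to 16.4 CPM. Without it the spheroid means of RN7SL2 and RN7SL1 were 12.1 ± 3.72 and 13.4 ± 2.63 CPM (n = 3), and the log2 fold changes of RN7SL2, RN7SL1 and RN7SL3 were -6.35, -6.07 and -5.01. These RNAs carry no poly(A) tail and exist in many near-identical copies, so their levels in a poly(A) library are uncertain. Among protein-coding genes, CHST9 (chromosome 18, 26906481 to 27185308), a sulfotransferase, was 12.3-fold lower in spheroids, with 187 ± 9.78 CPM in adherent cells and 15.1 ± 2.97 CPM in spheroids. CPA4 (chromosome 7, 130293161 to 130324180), a carboxypeptidase, was 9.85-fold lower, the kallikrein peptidase gene KLK13 (chromosome 19, 51055626 to 51065679) was 8.10-fold lower, and CCN2 (chromosome 6, 131948176 to 131951372), a matricellular protein gene that YAP activates, was 5.70-fold lower.

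**Figure D2:**
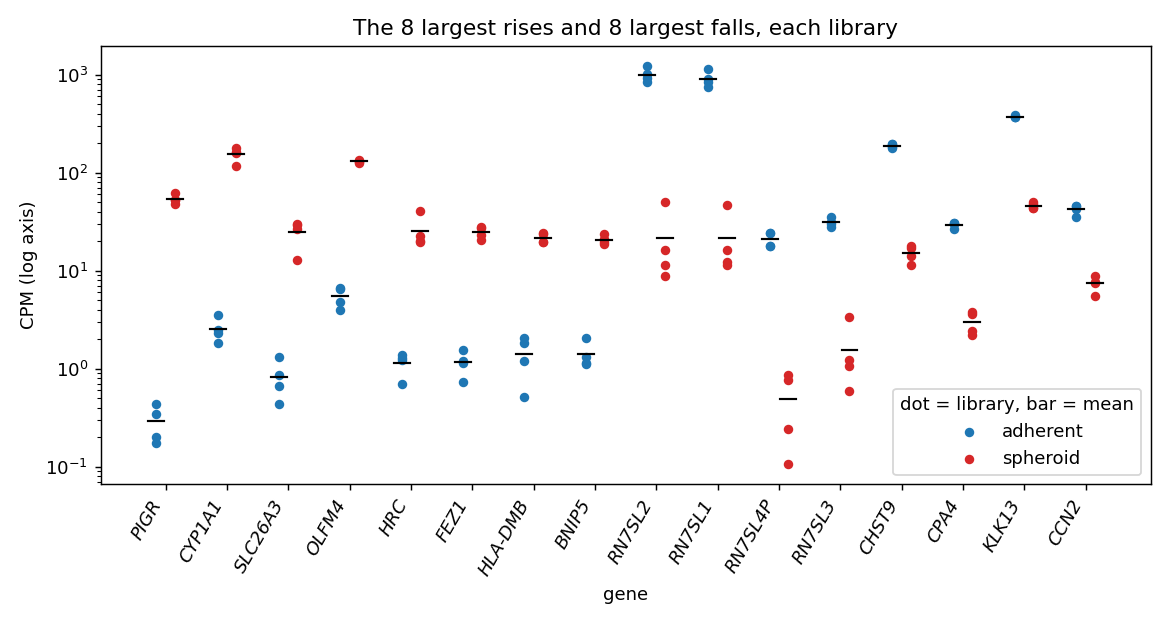
CPM on a log axis (vertical) of the 8 genes with the largest rises and the 8 with the largest falls (horizontal), with a dot per library coloured by group and bars at the group means of 4 libraries. PIGR means were 0.290 CPM in adherent cells and 53.4 CPM in spheroids, and RN7SL2 means were 999.5 and 21.7 CPM.

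Genes of cell division were lower in spheroids. All 17 genes of DNA replication and the G1/S transition and all 19 of G2 and mitosis fell, with median log2 fold changes of -1.10 and -1.27 (camera adjusted p = 4.15e-12 and 4.33e-14; adjusted p = 0.225 and 0.246 with an estimated correlation). RRM2, a subunit of ribonucleotide reductase, was 4.75-fold lower (373 ± 33.2 to 78.5 ± 13.9 CPM), and UHRF1, which maintains DNA methylation at replication, was 4.46-fold lower. CENPE, a kinetochore motor, was 5.67-fold lower and the cyclin gene CCNA2 was 4.08-fold lower. MKI67, the gene of the proliferation marker Ki-67, went from 297 ± 38.9 to 82.8 ± 19.5 CPM (log2 fold change -1.85, SE 0.17, edgeR adjusted p = 1.77e-05). All 7 measured replication-dependent histone genes fell, with a median of -1.45 (camera adjusted p = 1.41e-06; adjusted p = 0.0818 with an estimated correlation), among them H2BC12, 5.34-fold lower, and H2AC6, 2.74-fold lower; most transcripts of this class also lack a poly(A) tail.

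Targets of YAP and SRF, transcription regulators that respond to attachment and the actin cytoskeleton, were also lower. Of 18 measured, 11 fell, 1 rose and 6 did not pass the test (median -0.81, camera adjusted p = 7.42e-06; adjusted p = 0.29 with an estimated correlation). None rose without adherent replicate 2 or 3 or spheroid replicate 2 or 4. Besides CCN2, AMOTL2 was 3.88-fold lower. Of 17 integrin and focal adhesion genes, 7 fell and 4 rose (median -0.34, camera adjusted p = 0.42). Without spheroid replicate 1, 9 fell and 8 rose (median -0.12), and after GC correction 8 fell and 7 rose (median -0.04). The mean of that list was 6.39 log2 CPM in spheroid replicate 1 and 6.75 to 6.78 in the other spheroids. FERMT2, an activator of integrins, was 2.08-fold lower and ITGB8 1.93-fold lower, while ITGB6 rose 4.49-fold. Of 14 collagen, laminin and matrix genes, 6 fell and 5 rose (camera adjusted p = 0.477): COL6A1, a chain of collagen VI, rose 9.90-fold from 38.0 ± 1.21 to 377 ± 101 CPM, whereas THBS1 was 2.40-fold and COL12A1 1.79-fold lower.

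Epithelial markers were mostly higher. Of 14 measured, 8 rose and 4 fell, with a median of 0.70 (camera adjusted p = 0.036; adjusted p = 0.225 with an estimated correlation). The claudin gene CLDN7 rose 4.51-fold and EPCAM, an epithelial adhesion molecule, rose 2.42-fold to 1062 ± 155 CPM, while the keratin gene KRT18 was 1.92-fold lower. The call of this list ended in 9 of the alternatives, among them without spheroid replicate 1 (median 0.77, camera adjusted p = 0.179) and after GC correction (median 0.73, camera adjusted p = 0.0899), with a range of 0.00177 to 0.190 over all alternatives. With the filter at a mean of 10 CPM its median was only 0.20 (camera adjusted p = 0.190). Of 7 measured mesenchymal markers, 2 rose and 2 fell (median -0.03, camera adjusted p = 0.95). Without 1 library that median ranged from -0.13 (spheroid replicate 4 left out) to 0.14 (spheroid replicate 1 left out). Among them TAGLN, an actin-binding protein and SRF target, was 4.55-fold lower.

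Of 12 fatty acid synthesis and desaturation genes, 8 fell and 2 rose (median -0.55, camera adjusted p = 0.00222; adjusted p = 0.29 with an estimated correlation). Only 1 rose without adherent replicate 1 or 3 or spheroid replicate 2, 3 or 4. The desaturases FADS2 and SCD were 5.29-fold and 3.35-fold lower, and ACSS2, which makes acetyl-CoA from acetate, rose 1.45-fold. Of 22 genes of cholesterol synthesis and uptake, 12 fell and 3 rose, but the list did not pass camera (median -0.48, adjusted p = 0.0656). In this list 6 rose without spheroid replicate 1. It was called without adherent replicate 1, 3 or 4 or spheroid replicate 4 (camera adjusted p = 0.0440, 0.0479, 0.0454 and 0.0471), with a range of 0.00318 to 0.243 over all alternatives. IDI1 was 1.76-fold lower and TM7SF2 rose 1.83-fold, with 89.2 CPM in spheroid replicate 1 against 45.9 to 49.3 CPM in the other spheroids. Of 17 glycolysis genes, 11 fell and 3 rose (median -0.38, camera adjusted p = 0.115); this list was called without spheroid replicate 1 (adjusted p = 0.0021) and after GC correction (adjusted p = 0.00583), with a range of 3.11e-05 to 0.266 over all alternatives. HK2 and LDHA were 2.67-fold and 2.09-fold lower and the enolase gene ENO2 rose 2.80-fold.

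Genes of the hypoxia response moved both ways: of 15 measured, 4 rose, 4 fell and 7 did not pass the test (median -0.07, mean 0.27, camera adjusted p = 0.907). Without 1 library that median ranged from -0.15 (adherent replicate 4 left out) to 0.06 (adherent replicate 1 left out), and it was 0.03 without spheroid replicate 1. VEGFA, an angiogenic growth factor, rose 3.80-fold and KDM3A rose 1.54-fold, while LOX, a collagen crosslinking enzyme, was 2.80-fold lower. Of 19 nuclear-encoded genes of oxidative phosphorylation, 9 rose and 3 fell (camera adjusted p = 0.397), with NDUFB8 and COX6C 1.86-fold and 1.77-fold higher and NDUFS1 1.30-fold lower. In this list 10 rose and 5 fell without spheroid replicate 1, and 5 rose and 1 fell without adherent replicate 4. The number falling was also 1 without adherent replicate 2 or 3. NDUFS1 was not called with an offset for effective length (log2 fold change -0.16, edgeR adjusted p = 0.419, the highest over all alternatives) or without any 1 of the adherent replicates (edgeR adjusted p = 0.0633, 0.0529, 0.0678 and 0.0622). Of 13 mitochondrially encoded subunits, 2 fell, MT-ATP8 (926 ± 118 to 342 ± 249 CPM) and MT-ND4L (732 ± 41.8 to 274 ± 200 CPM), and the list did not pass camera (adjusted p = 0.398). Of these subunits 5 fell and 2 rose without spheroid replicate 1, 7 fell without spheroid replicate 2, and 2 fell and 2 rose after GC correction. None fell and 1 rose without adherent replicate 4 or spheroid replicate 4, and 1 fell without adherent replicate 1, 2 or 3. Both genes overlap a neighbouring mitochondrial gene, and neither MT-ATP8 nor MT-ND4L was called with an offset for effective length (edgeR adjusted p = 0.152 and 0.0611, with ranges of 0.000255 to 0.152 and 0.00038 to 0.0648 over all alternatives). Their calls also ended without adherent replicate 4 (edgeR adjusted p = 0.0752 and 0.0519) or spheroid replicate 4 (0.0872 and 0.0648), and that of MT-ATP8 without adherent replicate 1, 2 or 3 (0.0558, 0.0558 and 0.0596).

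Interferon-stimulated and lysosomal genes were higher in spheroids. Of 14 interferon-stimulated genes, 12 rose and 1 fell (median 1.30, camera adjusted p = 2.27e-07; adjusted p = 0.0796 with an estimated correlation). IFI6 rose 13.0-fold from 4.55 ± 0.732 to 59.1 ± 10.2 CPM and IFI27 rose 7.48-fold. Of 17 lysosomal genes, 13 rose and none fell in edgeR's test (median 0.60, camera adjusted p = 0.000203; adjusted p = 0.0796 with an estimated correlation), among them the lysosomal hydrolase genes NEU1 and HEXA, 2.89-fold and 2.50-fold higher. Of the lysosomal genes 1 fell without spheroid replicate 1 and 1 after GC correction.

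Of 18 NF-kB pathway genes and targets, 11 rose and 3 fell, and the list did not pass camera (median 0.68, adjusted p = 0.125). It was called with no filter beyond 1 count (adjusted p = 0.03, with a range of 0.03 to 0.439 over all alternatives), and after GC correction 9 rose and 6 fell. NFKB2 and RELB, subunits of the noncanonical pathway, rose 2.45-fold and 2.31-fold, RELB from 15.1 ± 1.32 to 34.9 ± 7.24 CPM, and the chemokine gene CXCL1 was 1.73-fold lower. RELA rose 1.33-fold (62.4 ± 2.78 to 83.2 ± 18.2 CPM, edgeR adjusted p = 0.0319), and after GC correction its log2 fold change was -0.01 (edgeR adjusted p = 0.943, with a range of 0.00761 to 0.943 over all alternatives). The call of RELA also ended without any 1 of the adherent replicates or without spheroid replicate 4 (edgeR adjusted p = 0.0646, 0.0804, 0.0866, 0.0578 and 0.066). Of 13 p53 target genes, 7 rose and 2 fell (camera adjusted p = 0.118, and 0.0264 without spheroid replicate 1, with a range of 0.0264 to 0.154 over all alternatives). Of these, 1 fell without any 1 of the adherent replicates or without spheroid replicate 4. GDF15 rose 5.73-fold, with 1155 CPM in spheroid replicate 1 against 673 to 703 CPM in the other spheroids, BBC3 rose 2.76-fold, and MDM2, which marks p53 for degradation, was 2.46-fold lower. Of 12 cell death regulators, 6 fell and 2 rose (median -0.47, camera adjusted p = 0.42). Of 13 measured without spheroid replicate 1, 7 fell and 4 rose (median -0.24). The survival genes BCL2L1 and CFLAR were 1.80-fold and 1.56-fold lower, and BMF, a death gene linked to loss of attachment, rose 3.28-fold.

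Several lists were fixed because the media differ in supplements and growth factors, and none of them passed camera with the main filter. With no filter beyond 1 count the metallothionein and iron lists were called (adjusted p = 0.0114 and 0.034, with ranges of 0.0114 to 0.162 and 0.034 to 0.266 over all alternatives). Of 16 selenoprotein genes, 7 rose and 1 fell (adjusted p = 0.279). Without spheroid replicate 1, 9 rose and 2 fell, and without adherent replicate 4, 4 rose and 1 fell. Their mean was 6.45 log2 CPM in spheroid replicate 1 against 6.26 to 6.29 in the other spheroids. SELENOM and GPX3 rose 4.32-fold and 3.00-fold and SELENOT was 1.49-fold lower. SELENOT was not called with an offset for effective length (log2 fold change -0.40, edgeR adjusted p = 0.0988, the highest over all alternatives). Of 9 iron genes, 5 fell (adjusted p = 0.134), including STEAP3, 2.32-fold lower, and IREB2, 1.80-fold lower. Of the iron genes 7 fell and 1 rose without spheroid replicate 1, and 3 fell without any 1 of the adherent replicates or without spheroid replicate 4. Of 5 measured metallothionein and zinc export genes, 4 rose and 1 fell (median 2.35, adjusted p = 0.115), with MT2A 4.66-fold higher and the zinc exporter gene SLC30A1 2.13-fold lower. The list mean was only 0.704 to 1.37 log2 CPM in adherent libraries, although MT2A and SLC30A1 had 4.40 and 18.9 CPM there. On average the other members thus lay near the floor in adherent cells and may have entered the test through the spheroid libraries. Of 16 ERK feedback genes, 6 rose and 3 fell (adjusted p = 0.279); FOS and EGR1, early response genes, rose 3.03-fold and 2.57-fold, SPRED2 was 2.05-fold lower, and the list mean was 6.03 log2 CPM in spheroid replicate 1 against 6.26 to 6.30 in the other spheroids. Of 17 amino acid response genes, 5 rose and 4 fell (adjusted p = 0.279). Without spheroid replicate 1, 6 rose and 7 fell, and after GC correction 7 rose and 7 fell. ATF3 and DDIT3, stress transcription factors, were 6.71-fold and 3.48-fold higher and PSAT1, of serine synthesis, 2.02-fold lower.

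Stress and developmental pathways also split within each list, and camera called none of them. Of 13 endoplasmic reticulum chaperone genes, 4 fell and 2 rose (adjusted p = 0.644). Without spheroid replicate 1, 5 fell and 4 rose, and after GC correction 4 fell and 4 rose. EDEM1 and SDF2L1 were 1.72-fold and 1.43-fold lower and HERPUD1 was 1.36-fold higher. Of 15 NRF2 targets, 5 fell and 4 rose (median 0.10, adjusted p = 0.51), and without spheroid replicate 1, 7 fell and 6 rose (median -0.10). The median was 0.03 without spheroid replicate 3. The aldo-keto reductase genes went both ways, AKR1B10 4.81-fold lower and AKR1C3 5.17-fold higher, and OSGIN1 was 1.73-fold lower. Of 11 heat shock genes, 5 rose and 3 fell (adjusted p = 0.398), and after GC correction 3 rose and 1 fell. HSPA1A and HSPA1B, near-identical copies, were 2.64-fold and 2.42-fold higher and the mitochondrial chaperonin HSPD1 1.82-fold lower. Of 11 TGF-beta and BMP response genes, 4 rose and 4 fell (adjusted p = 0.838), and 2 rose without adherent replicate 1, 2 or 3 or after GC correction. TGFBI rose 2.60-fold and SKIL, a repressor of SMAD signalling, was 3.03-fold lower. Of 12 Notch and Wnt response genes, 4 rose and 3 fell (adjusted p = 0.634), with HEY1 and NOTCH1 3.08-fold and 1.67-fold higher and the Wnt inhibitor gene DKK1 2.32-fold lower. DKK1 was not called with an offset for effective length (log2 fold change -0.81, edgeR adjusted p = 0.0768, the highest over all alternatives). NOTCH1 was not called after GC correction (log2 fold change 0.27, edgeR adjusted p = 0.154, the highest over all alternatives).

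Of 7 measured ovarian carcinoma markers, 5 rose and 1 fell (median 1.15, camera adjusted p = 0.0582), with FOLR1, a folate receptor gene, 3.22-fold higher. This list was called without adherent replicate 3 or 4 or spheroid replicate 3 or 4 (camera adjusted p = 0.0418, 0.0452, 0.0371 and 0.0181), with a range of 0.0181 to 0.156 over all alternatives. None fell without any 1 of the adherent replicates or of spheroid replicates 2 to 4. MUC16, which encodes CA-125, had at most 4 rounded counts in any library and did not pass the filter. With no filter beyond 1 count MUC16 had a log2 fold change of -0.16 with SE 0.95 (edgeR adjusted p = 0.925). Of 11 stem-like cell markers, 5 fell and 4 rose (adjusted p = 0.538), and without spheroid replicate 1, 5 of 12 fell and 7 rose. BMI1 and PROM1, the gene of CD133, were 2.28-fold and 1.93-fold lower, and ALDH1A2 rose 4.18-fold to 197 ± 22.6 CPM. ALDH1A1 was abundant in both groups, 1683 ± 36.5 CPM in adherent cells and 1448 ± 69.2 CPM in spheroids (1.16-fold lower, edgeR adjusted p = 0.0192), and was not called after GC correction (edgeR adjusted p = 0.963, with a range of 0.000213 to 0.963 over all alternatives) or without spheroid replicate 4 (adjusted p = 0.0539). Its call also ended with upper-quartile or total count scaling (edgeR adjusted p = 0.104 and 0.092). The same held with no filter beyond 1 count and with the filter at a mean of 10 CPM (edgeR adjusted p = 0.0538 and 0.104). Of 8 measured genes in the list named drug efflux transporters, which also holds lipid exporters such as ABCG1, 6 rose and 2 fell (adjusted p = 0.301). Of these, 3 rose without adherent replicate 1 or spheroid replicate 3, and 1 fell without adherent replicate 1, 3 or 4. ABCG1 was 2.58-fold and ABCC4 1.55-fold higher, and ABCC1 was 1.38-fold lower. The list mean was 4.34 log2 CPM in spheroid replicate 1 against 4.97 to 5.07 in the other spheroids. Of 3 measured squamous and secretory markers 2 fell (adjusted p = 0.452), including SLPI, 1.43-fold lower. With 5 measured without any 1 of the adherent replicates or 4 without spheroid replicate 2, 2 rose. The calls of ABCC4 and SLPI ended in most fits without 1 library: that of ABCC4 without any but spheroid replicate 1 (edgeR adjusted p of 0.0518 to 0.0721) and that of SLPI without any but adherent replicate 4 and spheroid replicate 1 (edgeR adjusted p of 0.0503 to 0.0782). Over all alternatives their ranges were 1.4e-08 to 0.0721 and 1.74e-08 to 0.0857. Of 20 ribosomal protein genes, 5 rose and 3 fell (adjusted p = 0.679). Without spheroid replicate 1, 8 rose and 5 fell, and 1 fell without adherent replicate 2, 3 or 4 or spheroid replicate 3 or 4. RPS2 rose 1.33-fold and RPL10 was 1.75-fold lower. The list mean was 10.1 log2 CPM in spheroid replicate 1 against 9.76 to 9.77 in the other spheroids. RPS2 was not called after GC correction (log2 fold change 0.05, edgeR adjusted p = 0.595, with a range of 0.000475 to 0.846 over all alternatives) or without any 1 of the adherent replicates (edgeR adjusted p = 0.0807, 0.0578, 0.0735 and 0.0648).

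Of 5 measured fibroblast markers, 2 fell and 1 rose (median -0.17, camera adjusted p = 0.115), and none rose without adherent replicate 3 or spheroid replicate 2. The median was -0.32 without spheroid replicate 3. The growth factor receptor genes PDGFRA and PDGFRB were 5.20-fold and 2.22-fold lower. Camera called this list lower with the filter at a mean of 10 CPM (3 members, median -1.07, adjusted p = 0.016), with an offset for effective length (median -0.74, adjusted p = 0.0325) and with no filter beyond 1 count (median 0.15, adjusted p = 0.0494), with a range of 0.016 to 0.399 over all alternatives. Of 5 leukocyte markers, 2 rose and 2 fell (median -0.12, adjusted p = 0.644), and 1 rose without spheroid replicate 4. CD68, a protein of lysosomes and endosomes, rose 12.4-fold to 74.6 ± 20.4 CPM, while LYZ, the lysozyme gene, was 1.63-fold lower. All 3 measured endothelial markers rose (camera adjusted p = 0.0656, and 0.0410 without adherent replicate 3, with a range of 0.0410 to 0.265 over all alternatives), with PECAM1 1.53-fold higher. PECAM1 was not called with an offset for effective length (log2 fold change 0.49, edgeR adjusted p = 0.184, the highest over all alternatives). Of 5 ciliated cell markers, 3 rose (adjusted p = 0.118), and the list was called with no filter beyond 1 count (adjusted p = 0.034, with a range of 0.034 to 0.355 over all alternatives).

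**Figure D3:**
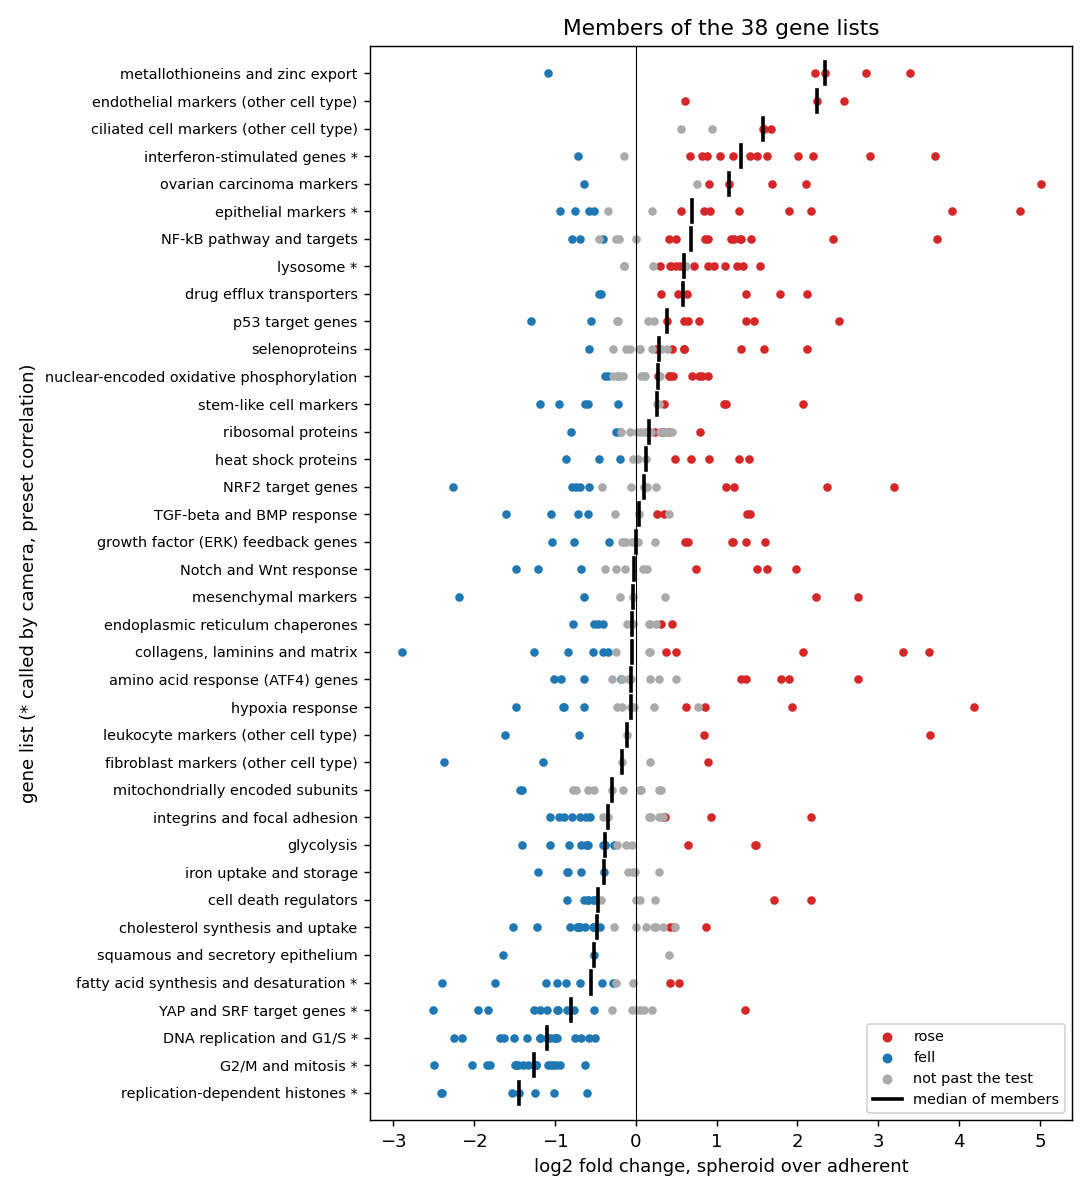
Log2 fold change, spheroid over adherent (horizontal), of the tested members of 38 gene lists (vertical), ordered by median, with a dot per gene coloured by whether it rose, fell or did not pass edgeR's test, a black bar at the median and * at the 8 lists called by camera. The lowest median is -1.45 for replication-dependent histones and the highest 2.35 for metallothioneins and zinc export.

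In total camera called 8 of the 38 lists, 3 higher and 5 lower, and with an estimated correlation it called none (lowest adjusted p = 0.0796). Fry, which asks whether a list's genes move on balance one way without comparing them with other genes, called 29 lists, and 36 for change in either direction. Adjusted over the list alone, the counts of rising and falling genes were the same for 29 lists. In the other 9 lists they moved, adjusted over the list alone, to 4 rising cholesterol genes, 5 falling oxidative phosphorylation genes, 0 falling mitochondrially encoded subunits, 8 falling integrin genes, 7 rising ERK feedback genes, 14 rising lysosomal genes, 6 rising ovarian carcinoma markers, 2 falling ribosomal protein genes and 4 rising ciliated cell markers. The median and the mean differed in sign for 8 lists, none of them called: hypoxia, mesenchymal markers, matrix, amino acid response, TGF-beta and BMP, Notch and Wnt, cell death and leukocyte markers. With upper-quartile scaling the medians of the hypoxia, mesenchymal, matrix, amino acid response, endoplasmic reticulum and Notch and Wnt lists turned positive (0.02 to 0.06), where this scaling shifted all genes by a median of 0.08. Some medians also changed sign without 1 library. That of the amino acid response list was 0.04 without spheroid replicate 2, and that of the Notch and Wnt list was 0.08 without adherent replicate 1 and 0.00 without spheroid replicate 4. That of leukocyte markers was 0.78 to 0.90 without any 1 of the adherent replicates, and 0.36 and 0.39 without spheroid replicate 2 or 3, and it was -0.24 without spheroid replicate 1. That of squamous and secretory markers was 0.37 to 0.43 without any 1 of the adherent replicates and 0.07 without spheroid replicate 2.

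For 4 fixed measures of depth and composition the exact two-sided permutation test gave adjusted p-values of 0.686 to 0.8286, and a single fully separated measure would reach no less than 0.114. Total expected counts were 12.7 ± 1.82 M in adherent and 10.5 ± 1.51 M in spheroid libraries (n = 4 each, exact p = 0.171, adjusted 0.686). Mitochondrially encoded genes took 4.25 ± 0.352% and 4.59 ± 1.41% of counts (exact p = 0.8286, adjusted 0.8286), and the 10 most abundant genes took 7.49 ± 0.200% and 8.02 ± 1.05% (exact p = 0.4, adjusted 0.724). Genes with at least 1 count numbered 22640 ± 415 and 22835 ± 415 (exact p = 0.543, adjusted 0.724). The unadjusted exact p was 0.0286, the smallest the test can give, for total counts without spheroid replicate 2, for the share of the 10 most abundant genes without spheroid replicate 1, and for genes at a TPM of at least 1, which numbered 14769 ± 101 and 15231 ± 146 (n = 4 each). Gene length less effective length, a measure of fragment size, was 166 to 179 bases in adherent libraries, 170 bases in spheroid replicate 1 and 193 to 199 bases in the other spheroids.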

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

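Tests chosen only after the result was seen are those of GC content, adherent material and depth for spheroid replicate 1, both tests on the cell cycle lists and both on the 7SL genes. A value was singled out where the highest or lowest of a group's 4 libraries stood off from the other 3 by more of the group's range than Dixon's critical value for 4 samples. Of 300 groups of values examined 30 were singled out, where chance gives about 15 (1 in 20), and 16 of the 30 lay in spheroid replicate 1.

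Spheroid replicate 1 stood apart in list means and in named genes. Its mean was lowest of the spheroids for integrins and focal adhesion (6.39 log2 CPM), ERK feedback genes (6.03) and drug efflux transporters (4.34), and highest for selenoproteins (6.45) and ribosomal proteins (10.1). It was also highest for HRC (40.4 CPM), RN7SL1 (46.4), TM7SF2 (89.2), GDF15 (1155), SELENOM (59.6), SLPI (95.0), RPS2 (2197) and CD68 (105), and lowest for SELENOT (51.6), IREB2 (33.9) and ABCC1 (78.0). The depth of spheroid replicate 1, 9.30 M, argues against depth as the cause: replicate 4, with 9.06 M, correlated with replicates 2 and 3 better by 0.0360. RNA from adherent cells would give a negative slope of its deviation on the difference between the groups, and the slope was 0.125 with a spread of 0.0268 between the other spheroids. Its deviation followed transcript GC content across genes (rank correlation 0.615), so coverage that depends on GC content may account for part of it, but after GC correction its highest correlation with another spheroid was 0.965, still under the 0.985 of the lowest pair of the others, which argues against GC content as the whole cause. Its deviation also followed transcript length across genes (rank correlation -0.356, and -0.288 after GC correction), so RNA quality or coverage along transcripts stays open for the rest, and no biological explanation was tested, since the design gives none within a group. The fold changes between the groups followed GC content too (correlation across genes 0.347, and 0.216 without spheroid replicate 1). Leaving out this library thus lowered that trend but did not remove it.

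The cell cycle lists fell in every spheroid library. GC content alone is argued against: after GC correction the median log2 fold change of the 36 genes was -1.18 with an SD of 0.47 over genes, against -1.24 before, and it was -1.28 without spheroid replicate 1. Whether the medium or the loss of attachment goes with the fall cannot be told apart, because 0 of the 8 libraries cross medium and attachment, and the difference between the cultures may rest on either. Fragment size also went with the group, at 166 to 179 bases in adherent libraries and 193 to 199 in spheroid replicates 2 to 4. Spheroid replicate 1, with 170 bases, had means of 5.36 and 5.15 log2 CPM for the 2 lists. The other spheroids had 5.12 to 5.36 and 4.85 to 5.22. A part of library preparation in the difference between the groups was not tested.

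The 7SL RNA genes fell most. Reads moved between copies cannot make the fall, since the CPM summed over the genes named RN7SL also fell, from 1974 ± 341 to 50.3 ± 39.9, and to 30.6 ± 6.97 without spheroid replicate 1. The difference between the groups' means of log2 values over the libraries was -5.55 with an SE of 0.50, and -6.02 without spheroid replicate 1. Carry-over of RNAs without poly(A) tails into the adherent libraries could lower such RNAs in spheroids as a class. The median of 4 other such RNAs was 1.33 with an SD of 0.93, opposite to that, and 0.62 without spheroid replicate 1, but only 1 of them, RN7SK, had a mean of at least 10 CPM and 13 of 17 listed were too low to test. All 7 measured replication-dependent histone genes, most of whose transcripts lack a tail too, fell (median -1.45), as carry-over would have it, but genes of cell division fell as well, so carry-over and a change in the cells cannot be told apart.

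The remaining 14 values lay in adherent libraries. Replicate 4 had the highest total, 15.4 M expected counts, and the highest MT-ND4L, 794 CPM. Replicate 1 was highest for mesenchymal markers (4.49 log2 CPM), KLK13 (392 CPM) and ENO2 (23.0 CPM), and lowest for HSPD1 (1313 CPM), PDGFRA (107 CPM) and PDGFRB (12.5 CPM). Replicate 2 was lowest for NF-kB genes (3.66 log2 CPM), VEGFA (62.1 CPM), HK2 (62.6 CPM) and PROM1 (188 CPM) and highest for SCD (394 CPM), and replicate 3 was lowest for H2AC6 (33.8 CPM).

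For the counts of genes the real division of the libraries ranked first among the splits. Of the 35 splits of the 8 libraries into 4 and 4, only 1, the real one, gave as many as 8020 changed genes or 1398 beyond 2-fold, and the highest other split gave 0 in both. The other splits mix the groups, so the difference between the groups adds to the spread within each side, which lowers their counts. The smallest share the splits can give is 1 of 35, so they rank the real division first but cannot exclude chance. For the number of gene lists the splits do not decide either. Of the 35, 11 called as many lists as the real one, 8, and the highest other called 10. Those among the 11 other than the real one each set most libraries of 1 group against most of the other. They thus keep part of the real contrast. Splits with the groups mixed evenly hold no such contrast, yet they called up to 6 lists with 0 changed genes. Camera with the preset correlation can thus call lists in these data without a difference between the groups. Its adjusted p-values may be too small.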

How the results depend on the processing

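The GC corrections were chosen after seeing the data; the other alternatives were fixed before. The count of changed genes stayed within 1.5 times of 8020 in every alternative, from 5355 with the filter at a mean of 10 CPM, which tested fewer genes (9541), to 10271 without spheroid replicate 1. The 4199 higher and 3821 lower genes became 4801 and 3279 with upper-quartile and 4653 and 3275 with total count scaling, and lower genes outnumbered higher ones with limma-trend (3960 higher, 4111 lower) and in the fits with GC correction (4221 and 4312, 4940 and 5280 without spheroid replicate 1, 3922 and 4093 with the replicate block). Leaving out 1 library gave 6982 to 10271 genes, 1197 to 1649 beyond 2-fold and 8 to 11 lists. Beyond 2-fold, 1398 genes became 552 with the filter at a mean of 10 CPM, 949 with the DESeq2 Wald test, 920 with limma-voom and 521 with limma-trend on the deposited table. The cause was not tested for DESeq2 or limma. The number of lists called was 17 with no filter beyond 1 count, where 31828 genes form the background, 0 with an estimated correlation and 29 with fry, and 7 to 11 otherwise. Of 107 called named genes, 95 kept their call and direction in all 21 settings run. The other 12 lost their call in at least 1 setting. The log2 fold change of RELA reversed to -0.0079 after GC correction, -0.025 with GC correction and without spheroid replicate 1, and -0.010 with GC correction and the replicate block, and that of RPS2 to -0.011 with GC correction and without spheroid replicate 1, none past the threshold. Leaving out 1 library also ended calls of NDUFS1, MT-ATP8, MT-ND4L, ABCC4, SLPI and RPS2, whose adjusted p then reached at most 0.0872. Of the 8020 genes, 6802 kept their call and direction after GC correction and 108 changed sign. With an offset for effective length 6803 genes were called, and of the 8020 genes 6449 kept their call and direction and 43 changed sign. Same-numbered libraries of the groups did not clearly deviate together (correlations across genes of -0.01, -0.05, 0.05 and 0.05). Spheroid replicate 1 weighs on the spheroid deviations, so these values do not show whether the numbers pair the libraries. With a replicate block 7487 genes changed, 1256 beyond 2-fold, and 8 lists were called. The epithelial list was lost (camera adjusted p = 0.0695) and the ovarian carcinoma list was gained (camera adjusted p = 0.0395). The calls of RPS2 and ALDH1A1 ended (edgeR adjusted p = 0.0502 and 0.0518). Of the named genes and lists the block changed no other call. Leaving out spheroid replicate 1, or the GC correction, moved the numbers of rising and falling genes in several lists, among them the integrin list. The simulation changed 200 of 14829 genes, so its recovery does not carry over to a comparison with 8020 calls. With no filter beyond 1 count the SE of MUC16, with at most 4 counts in any library, was 0.95, so a 2-fold change in it was not detectable at this depth. The exact test of library measures decides little, since a single measure with the smallest p, 0.0286, has an adjusted p of 0.114.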

Other observations

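The lists of intestinal markers, class II genes and receptor targets were drawn up after the largest changes were seen and before the values of their members were, and the test of gene families and the other genes named here were chosen after the data were seen. Spheroids showed more of the genes that mark intestinal epithelium. CEACAM5 rose from 240 ± 15.5 to 2743 ± 234 CPM, CEACAM7 from 64.1 ± 5.12 to 900 ± 118 CPM, and FCGBP, a mucus protein gene, from 21.5 ± 1.86 to 171 ± 27.3 CPM. A hypothesis that a wider set of such markers rose held in its test: of 13 further markers measured among 22, 10 rose and 1 fell, with a median log2 fold change of 1.199 (camera p = 1.94e-07; p = 0.00492 with an estimated correlation), and KRT20 and FABP1 had log2 fold changes of 3.37 and 3.33. HNF4A, a transcription factor of that lineage, fell (log2 fold change -0.72). This is consistent with a wider shift toward an intestinal-type profile in these spheroids, as a hypothesis found in the same data.

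Gene families were compared by symbol. Among 222 groups of genes sharing a symbol root, with at least 8 tested members each, camera called 8, 6 higher and 2 lower, and none with an estimated correlation. All 11 HLA genes rose (median log2 fold change 2.51, camera adjusted p = 3.27e-10, and 0.537 with an estimated correlation). All 9 ABCA transporter genes rose (median 1.84), and 9 of 14 matrix metalloproteinase genes rose and 1 fell. All 10 genes with the symbol root MCM fell (median -1.13), and several of them are also in the list of DNA replication genes. Those HLA genes include near-identical copies, and 5 of the 11 had an adherent mean under the level of 0.855 CPM at which the filter admits a gene, so they entered the test through the spheroid libraries. The same holds for the other class II genes, which could have risen together with HLA-DMB: the 5 tested of 10 listed had a median log2 fold change of 3.34, but all 5 lay under that level in adherent cells, HLA-DMA at 0.207 CPM and CD74 at 0.0168 CPM, so the test does not decide. With no filter beyond 1 count, 6 of the 9 with any count rose and none fell in edgeR's test, near the floor in adherent cells.

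CYP1A1 is a target of the aryl hydrocarbon receptor, and its other targets could have risen with it. The median log2 fold change of 7 of them was 0.14 with an SE of 0.60 for the median, and 3 rose and 2 fell (camera p = 0.0437; p = 0.241 with an estimated correlation), so the test does not decide. Camera p was 0.000779 without spheroid replicate 1 and 0.0106 after GC correction, with medians of 0.13 and 0.16. With no filter beyond 1 count, which adds 2 genes under the filter, the median was 1.05 and 4 of 9 rose and 2 fell. Camera p was then 0.00638, and the median rests on those 2 genes. CYP1B1, AHRR and TIPARP had log2 fold changes of 2.37, 2.23 and 1.67, and NFE2L2 and SERPINB2 of -0.55 and -0.44.

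Other large changes outside the named genes were DUOX2, which makes hydrogen peroxide (4.88 ± 0.706 to 64.2 ± 11.9 CPM), TXNIP (63.7 ± 6.51 to 638 ± 74.1 CPM) and SAT1, of polyamine breakdown (14.2 ± 1.43 to 180 ± 14.7 CPM). FKBP11 went from 157 ± 10.0 to 31.3 ± 2.41 CPM, APOB from 84.4 ± 12.9 to 18.5 ± 4.11 CPM and the nuclear RNA MALAT1 from 226 ± 67.5 to 54.8 ± 8.43 CPM.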
